A study of Arabidopsis thaliana and Oryza sativa with 18 samples.

How the data were processed

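Gene expression was measured by RNA sequencing in 18 libraries, 9 from Arabidopsis thaliana and 9 from Oryza sativa (rice). Per the labels, the Arabidopsis material was whole seedlings of the wild type C24 and of the mutants ldl2 and mbd8, collected after 12 days on agar medium with 8 h of light and 16 h of dark at 22 °C. The rice material was leaves of 50 days from Nip (Nipponbare) and from the mutants hd18 and mbd715mbd709, raised in a chamber at 28 °C with 14 h of light and 10 h of dark. Each genotype had 3 libraries. The labels do not say that the libraries of a group came from separate plants or cultures, so the p-values measure only the spread between these samples, which may be technical. They also do not name the line in which each mutant was made, nor the gene identifiers behind mbd715mbd709, so the level of those targeted genes was not checked.

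RNA was extracted with TRIzol and sequenced as paired reads of 150 bp on an Illumina NovaSeq, per the labels. The submitters' processing notes name bcl2fastq, STAR, HISAT2 and edgeR, and the genome builds TAIR10 and IRGSP-1.0, without versions, roles or settings. The counting tool, the gene annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. The deposited tables, 1 for each species, hold a signal that is a library-size equalised read count per gene, so it is neither a raw count nor a CPM value. This was inferred from the values. Only 0.159% of the Arabidopsis and 0.164% of the rice values of at least 0.5 were whole within a tolerance of 0.001. Genes with 1 to a few reads in single libraries fell on fixed steps, and 18 of 18 low-read patterns held out from the fit were found within that tolerance in each species, under an adjustment applied within each group of 3 with a dispersion of 0.00780 in Arabidopsis and 0.0227 in rice. Because of this unit, the count test planned for raw counts was not used, and the branch planned for normalised values was.

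The deposited values summed to 19.2 to 20.3 Mreads (mega-reads) per Arabidopsis library and 32.3 to 36.3 Mreads per rice library. With the fitted scaling undone, the totals were 18.1 to 23.2 and 32.2 to 34.7 Mreads. Even read numbers made up 28.0 to 33.5% of the single-library values of 1 to 8 reads in Arabidopsis and 47.2 to 55.0% in rice, so the 2 tables differed in how low read numbers were distributed. Replicate libraries differed by 3.86 to 11.8 times the Poisson variance in Arabidopsis and by 7.44 to 43.0 times in rice, so no pair of libraries matched within sampling noise. The 10 most abundant genes held 8.59 to 9.62% of the signal in Arabidopsis and 9.28 to 12.2% in rice. The median SD within a group was 0.138 on the log2 scale in Arabidopsis and 0.185 in rice.

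The tables list 32548 Arabidopsis and 38993 rice genes, of which 7384 and 8719 were at 0 in every library. All 32548 Arabidopsis identifiers were found in the reference gene table of the TAIR10.1 assembly, which gave symbols, coordinates and annotation phrases. The rice table held 37864 identifiers of the RAP form, 1129 of other forms and 1 line naming no gene, which was left out. The rice files do not pair identifiers with names, and no rice coordinates were used. Rice genes were named only where they stood with their identifier in a prepared list. Overlapping genes are uncertain in the Arabidopsis table. Of 3915 protein-coding genes at 0 throughout, 487 (12.4%) had at least 90% of their exon bases inside another listed gene, against 52 of 23529 others (0.221%, odds ratio 64.1). MYC2 (98.5% overlap), F3H (93.8%), COL1 (100%) and SPL15 (100%) were among the genes listed at 0, and FLC (68.1%) was not.

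Each species was fitted alone with limma 3.58.1 in R 4.3.3, using an intensity-dependent variance trend on log2(value + 1) over all 9 libraries, so that the 3 groups shared an estimate of the spread. A gene was tested if its value reached 10 in at least 3 of the 9 libraries, which kept 19985 Arabidopsis and 22624 rice genes. Adjusted p-values are Benjamini-Hochberg values from limma with a threshold of 0.05. Log2 fold changes are on the log2(value + 1) scale and understate the change of low genes. The comparisons were each mutant against its wild type and the 2 mutants of a species against each other. Calls shared by the mutants of a species were counted per direction and set beside the number that independent lists would share and beside 100 simulated draws. Each draw made all 9 libraries anew with no changed gene, and both mutants were compared with the same drawn wild-type group. Genes were drawn independently, so few shared calls could arise, and the draws do not measure what the real wild-type libraries add. With 3 wild-type libraries, these could not be split for separate comparisons, so part of any excess may come from the shared controls.

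The named genes followed a rule. It took the mutated genes and their relatives, the 8 largest rises and 8 largest falls with no overlap between the groups and a mean of at least 1 CPM, every called member of the flowering lists, up to 4 members of each other list, up to 6 shared genes per direction and 5 genes per direction in the direct contrast. List members named beyond these numbers, such as SALT, DIP1, WRKY62 and LOX2, and the examples from annotation phrases were chosen after their values were seen. The values of 1 list member are not reported here, although it stayed in the list counts. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with fry and an estimated correlation as alternatives. A list needed 3 tested members. The Arabidopsis lists were mutated genes and their families, flowering promoters, flowering repressors, circadian clock, histone and DNA methylation enzymes, salicylic acid defence, jasmonate response, heat shock proteins, cold, drought and abscisic acid response, iron homeostasis, photosynthesis, flavonoid and anthocyanin synthesis, glucosinolate synthesis, root markers, floral organ markers and seed markers. The rice lists were mutated genes and their families, flowering promoters, flowering repressors, circadian clock, histone and DNA methylation enzymes, defence and phytoalexin synthesis, heat shock proteins, drought and abscisic acid response, photosynthesis, leaf senescence, floral organ markers and meristem markers. Sample groups, tests, lists, the rule for named genes and most alternatives were chosen before the data were examined. A further list of 11 touch and rapid wound genes was written later, before its values were seen.

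Annotation phrases from the Arabidopsis reference were tested with Fisher's exact test for 253 phrases of 10 to 500 genes, over the 8758 tested genes that carry a phrase. Notes that gave only a number of processes were left out, so a gene without a phrase may still belong to that process. Clustering of changed genes around the mutated locus was tested within 2 Mb, with 1 and 5 Mb as alternatives. The fitting step was tested on simulated data with 200 changed genes. For ldl2 against C24, over 19985 genes, it recovered 21, 36, 45 and 48 of 50 genes changed by 0.5, 1, 1.5 and 2 on the log2 scale, with 16 false calls among 166. For hd18 against Nip, over 22624 genes, it recovered 7, 38, 38 and 47 of 50, with 13 false calls among 143.

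Alternatives changed 1 choice at a time, except where 2 are named: another scaling by median ratios, no filter on low values, a filter at a mean of 1 CPM, only the 2 groups compared, the replicate number as a block, a pseudocount of 0.1 without a filter, and each library left out in turn, also for annotation phrases and list counts. The restriction of the median-ratio scaling to genes of at least 1 in every library was set after a first run. A pseudocount of 0.1 with the filter kept, and precision weights (voom), were added after seeing the data. The weights were first run on library totals, and a form using the fitted depth was added after that result was seen, so both are given. Computation outside R used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and statmod 1.5.0 served the set tests.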

Results

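Transcript levels were compared in 2 plant species. The study's title presents MBD8, a protein with a methyl-CpG-binding domain, as a cofactor of LDL2, an LSD1-type histone demethylase, in the timing of flowering. Arabidopsis seedlings of 12 days were C24 wild type, ldl2 or mbd8, and rice leaves of 50 days were Nip wild type, hd18 or mbd715mbd709, with 3 libraries per genotype. HD18 is a rice gene of the same amine oxidase family as LDL2, and the name mbd715mbd709 joins those of 2 MBD genes. Values are library-size equalised read counts, given as mean ± SD over 3 libraries, and adjusted p-values come from limma with Benjamini-Hochberg adjustment. Totals per library were 19.2 to 20.3 Mreads (mega-reads) in Arabidopsis and 32.3 to 36.3 Mreads in rice.

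The comparison of ldl2 with C24 asked which transcripts differ when LDL2 is mutated. LDL2 (AT3G13682, TAIR10.1 chromosome 3, 4478873 to 4481767) fell from 111.8 ± 5.42 in C24 to 57.0 ± 9.50 in ldl2 (log2 fold change −0.97, SE 0.162, adjusted p = 0.00789). Single ldl2 libraries held 67.6, 49.2 and 54.3, all below the lowest C24 value of 105.5, and the call was lost without ldl2 replicate 2 (adjusted p = 0.0564). MBD8 did not pass the test in ldl2 (log2 fold change 0.10, adjusted p = 0.811). TEM1 and TEM2, which encode RAV-type repressors of the florigen gene FT, rose. TEM1 went from 534 ± 61.4 to 1231 ± 152 (log2 fold change 1.204, SE 0.123, adjusted p = 0.000115) and TEM2 from 1161 ± 76.6 to 2802 ± 364 (1.26, SE 0.123, adjusted p = 7.93e-05).

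FT lay under the filter on low values and was not tested. Its values were 5.33, 8.49 and 9.71 in the C24 libraries, 0.73, 4.01 and 2.05 in ldl2 and 1.00, 3.17 and 1.01 in mbd8, so every mutant library was below every C24 library. SOC1, a MADS-box integrator of flowering signals, did not pass in ldl2 (326 ± 47.4 in C24, 261 ± 27.6 in ldl2, log2 fold change −0.32, adjusted p = 0.341). FLC, a MADS-box repressor of flowering, had a log2 fold change of −0.16 (adjusted p = 0.461), and 68.1% of its exon bases lie inside another listed gene. TEM1 and TEM2 were the 2 of 24 tested flowering repressors that rose, and 4 rose when adjusted over the list alone. The repressor list was higher as a set (camera adjusted p = 0.0196), which was lost without C24 replicate 2 (0.0624) and gave adjusted p = 0.296 with an estimated correlation. Among 19 tested flowering promoters limma called 0, with 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.108).

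**Figure D1:**
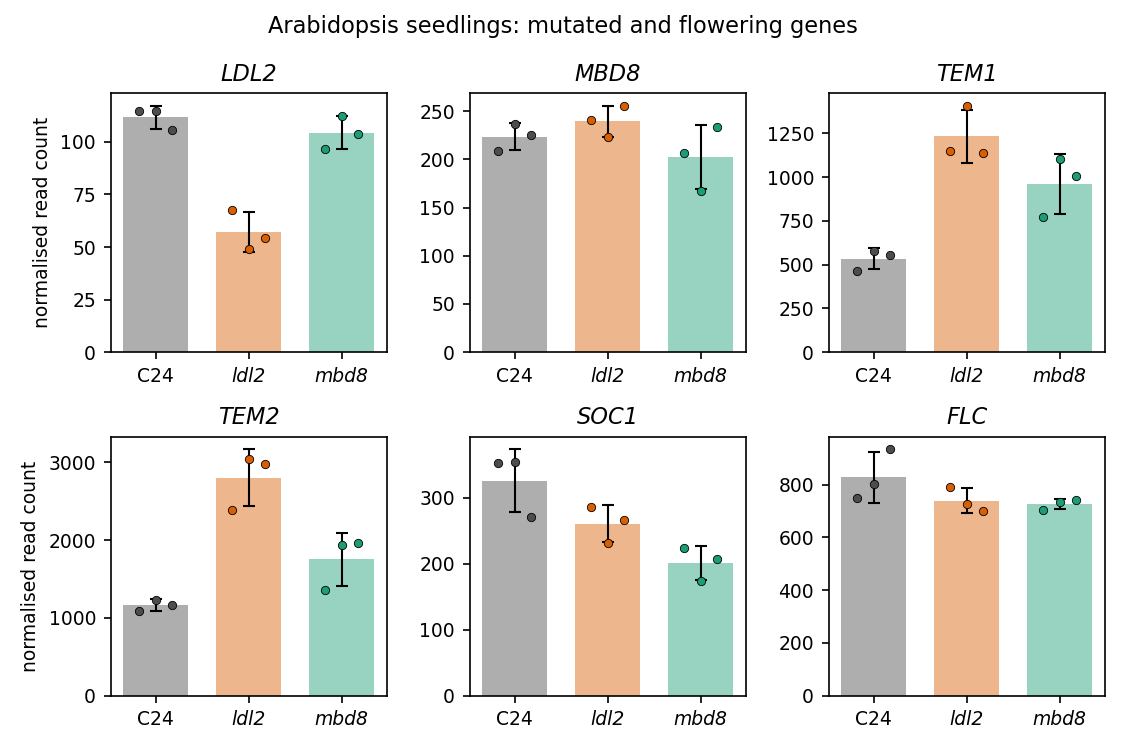
Library-size equalised read counts of LDL2, MBD8, TEM1, TEM2, SOC1 and FLC in C24, ldl2 and mbd8 seedlings; bars are means, error bars are the SD over 3 libraries and points are single libraries. LDL2 was lower in ldl2 alone, MBD8 was not lower in mbd8 by the test, and TEM1 and TEM2 lay above every C24 library in both mutants.

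The largest rises in ldl2 lay outside the flowering lists. AT2G15555, a non-coding RNA gene (TAIR10.1 chromosome 2, 6785904 to 6786976), went from 43.2 ± 6.16 to 1126 ± 117 (log2 fold change 4.68, SE 0.124, adjusted p = 1.62e-11). AT3G06955, annotated as a long non-coding RNA, rose by 3.57 (adjusted p = 0.000192). ORA47, an AP2/ERF transcription factor, rose from 57.7 ± 12.6 to 389.9 ± 97.9 (2.73, SE 0.309, adjusted p = 0.000279). DIC2, a mitochondrial dicarboxylate carrier, rose by 2.61 (adjusted p = 2.94e-05), CAF1a, a deadenylase, by 2.55 (adjusted p = 1.19e-05) and ERF104, another AP2/ERF factor, by 2.03 (adjusted p = 7.86e-08). ERF13 rose by 2.11 (adjusted p = 0.0251), a call lost without C24 replicates 1 or 3 or ldl2 replicates 2 or 3 (0.0659 to 0.144). AT3G62460 (chromosome 3, 23104665 to 23105650) rose by 2.08 (adjusted p = 0.000291). The largest fall was that of ARP9 (AT5G43500, chromosome 5, 17469490 to 17473619), an actin-related protein, from 548 ± 40.8 to 213 ± 31.6 (log2 fold change −1.37, SE 0.113, adjusted p = 1.96e-05). PRP2, a proline-rich protein, fell by 0.60 (adjusted p = 0.0347), which was lost without C24 replicates 1 or 2 or ldl2 replicates 2 or 3 (0.152 to 0.178).

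Some stress genes were among those that rose. Of 24 tested genes of cold, drought and abscisic acid response, 4 rose, and 7 did when adjusted over the list alone. They were ERD10, a dehydrin (log2 fold change 0.40, adjusted p = 0.00403), the NAC factor RD26 (0.67, 0.00865), NCED3, an enzyme of abscisic acid synthesis (1.18, 0.0128), and the cold-response factor CBF2 (2.05, 0.0128). The list was higher as a set (camera adjusted p = 4.07e-06), with adjusted p = 0.296 with an estimated correlation. The count of 4 dropped to 1 without C24 replicate 1, 1 without ldl2 replicate 2 and 2 without ldl2 replicate 3. RD26 was lost without C24 replicate 1 (0.0539) or ldl2 replicate 2 (0.0592), NCED3 without C24 replicates 1 or 2 or ldl2 replicates 2 or 3 (0.0555 to 0.082), and CBF2 without C24 replicate 1 or ldl2 replicates 2 or 3 (0.0619 to 0.11).

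Genes annotated with the response to chitin were enriched among the genes that rose in ldl2, with 8 of 53 against 0.303 expected by chance (Fisher's exact test, adjusted p = 1.16e-07), among them ATL2, RDUF1, RDUF2, CMPG2 and HSFB2A. This enrichment passed in every run with 1 library left out, while the 8 genes became 5 without C24 replicate 1, 5 without ldl2 replicate 2 and 5 without ldl2 replicate 3. The response to wounding held 4 of 61 (adjusted p = 0.0488) and passed in none of those runs, with an adjusted p of 1 without C24 replicates 1 or 2 or ldl2 replicate 3, 0.385 without C24 replicate 3, 0.257 without ldl2 replicate 1 and 0.927 without ldl2 replicate 2. In the same libraries 6 of 11 touch and rapid wound genes rose (median log2 fold change 1.25 over the 11). They were TCH2 (1.01), TCH4 (1.25), STZ (1.71), ZAT12 (1.45), ERF5 (1.66) and ERF6 (1.56). By limma TCH3 (0.38), CML37 (0.26), CML38, WRKY33 and WRKY40 did not pass (adjusted p = 0.457, 0.896, 0.11, 0.0517 and 0.0949). All 11 were above 0. TCH4 was lost without ldl2 replicate 2 (0.0642). For mbd8, limma called 0 of the 11 and 6 were higher at an unadjusted p under 0.05 (median 0.39).

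Salicylic acid defence genes were higher in ldl2 as a set (camera adjusted p = 0.0115), with WRKY46 as the 1 called member of 20 and 2 adjusted over the list alone. That test gave adjusted p = 0.497 with an estimated correlation and was lost without C24 replicate 2 (0.0624) or ldl2 replicate 2 (0.24), and WRKY46 (log2 fold change 0.79, adjusted p = 0.0314) was lost without C24 replicates 2 or 3 or ldl2 replicates 2 or 3 (0.0768 to 0.175). All 20 tested photosynthesis genes were below 0 (median −0.15, camera adjusted p = 2.23e-10), with adjusted p = 0.296 with an estimated correlation. RBCS2B, a Rubisco small subunit gene, was the 1 that fell (by 0.26, adjusted p = 0.0416), and 3 fell when adjusted over the list alone; its call was lost without C24 replicates 1 or 2 or ldl2 replicates 2 or 3 (0.107 to 0.233). Flavonoid and anthocyanin genes were higher as a set (camera adjusted p = 0.00633; adjusted p = 0.322 with an estimated correlation), with 1 call of 13, the glutathione transferase gene TT19 (0.72, adjusted p = 0.0256), which was also the 1 adjusted over the list alone. The set was lost without C24 replicate 2 (0.113) or ldl2 replicate 1 (0.0701), and TT19 without C24 replicates 1 or 2 or any ldl2 replicate (0.0556 to 0.107). Glucosinolate genes were higher as a set (camera adjusted p = 0.00138; adjusted p = 0.322 with an estimated correlation), 17 of 19 being above 0. The 1 call, over all genes and over the list alone, was CYP79B3, which converts tryptophan (0.36, adjusted p = 0.0212), and it was lost without any 1 of the 6 libraries (0.051 to 0.0996).

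The circadian clock list was lower as a set in ldl2 (camera adjusted p = 0.0378; adjusted p = 0.322 with an estimated correlation), although limma called 0 of its 23 genes, with 5 lower at an unadjusted p under 0.05. It was lost without C24 replicate 2 (0.207), ldl2 replicate 1 (0.0791) or ldl2 replicate 3 (0.079). Histone and DNA methylation enzymes did not pass as a set (camera adjusted p = 0.0928), but did without C24 replicate 1 (0.045). Their 38 tested members held 0 limma calls, 5 at an unadjusted p under 0.05, and 1 higher and 2 lower adjusted over the list alone. The families of the mutated genes did not pass as a set (camera adjusted p = 0.537; median 0.00, mean −0.07, test negative), with LDL2 as the 1 call of 14, over all genes and over the list alone. Jasmonate response did not pass (0.397) but did without ldl2 replicate 2 (0.019). Of its 18 tested genes limma called 0, with 3 at an unadjusted p under 0.05, and 1 was higher and 1 lower adjusted over the list alone. Heat shock proteins (0.343), iron homeostasis (0.273), root markers (0.233) and seed markers (0.459) did not pass, and 2 of 8 floral organ markers passed the filter, too few for a test.

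In total 200 of 19985 genes passed in ldl2, 163 higher and 37 lower, of which 66 changed at least 2-fold. Groups that do not overlap, which chance gives for 10% of genes, were found for 18.7% of those tested. The count of 200 became 101 without C24 replicate 1 (96 higher and 5 lower), 108 without C24 replicate 2 (103 and 5), 76 without ldl2 replicate 2 (71 and 5) and 90 without ldl2 replicate 3 (87 and 3), and the 37 lower became 60 without C24 replicate 3. With only C24 and ldl2 in the fit it was 313 (238 and 75). With the replicate number as a block it was 583 (342 and 241), so 58.7% of the calls were higher, against 81.5% in the main fit. Changed genes were not enriched within 2 Mb of LDL2 (8 of 925, Fisher's exact p = 0.865) or in any of 121 windows of 1 Mb (smallest adjusted p = 0.949), and no annotation phrase passed among the genes that fell (smallest adjusted p = 0.268).

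The comparison of mbd8 with C24 asked the same of MBD8. MBD8 (AT1G22310, TAIR10.1 chromosome 1, 7881503 to 7883824) itself was not lower by the test. The libraries labelled mbd8 held 206.4, 167.7 and 233.6 against 208.9, 236.5 and 224.8 in C24 (log2 fold change −0.15, adjusted p = 0.628), so transcript level did not check that label. AT2G15555 rose in mbd8 as well, to 965 ± 141 from 43.2 ± 6.16 (log2 fold change 4.45, SE 0.124, adjusted p = 3.31e-11). ROS1, a DNA demethylase, fell from 1226 ± 23.62 to 736 ± 67.9 (−0.74, SE 0.07, adjusted p = 0.000252), and FRO6, a ferric reductase, fell from 6589.7 ± 483 to 4262 ± 487 (−0.63, SE 0.079, adjusted p = 0.00438). CAF1a rose by 1.49 (adjusted p = 0.00655), ERF104 by 1.21 (adjusted p = 0.000136) and AT3G62460 by 1.80 (adjusted p = 0.00655).

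TEM1 rose in the libraries labelled mbd8, to 961 ± 170 from 534 ± 61.4 (log2 fold change 0.84, SE 0.123, adjusted p = 0.0124), which was lost without C24 replicate 1 (0.0889). TEM2 rose by 0.57 (SE 0.123, adjusted p = 0.0468), to 1752 ± 342, and SOC1 fell from 326 ± 47.4 to 201 ± 25.7 (−0.69, SE 0.132, adjusted p = 0.0349). TEM2 was lost without any C24 replicate or mbd8 replicates 2 or 3 (0.0765 to 0.181), and SOC1 without C24 replicates 1 or 2 or any mbd8 replicate (0.0509 to 0.19). FLC did not pass (−0.18, adjusted p = 0.328). SOC1 was the 1 called of 19 flowering promoters, over all genes and over the list alone (camera adjusted p = 0.377; median −0.01, mean 0.05, test negative). TEM1 and TEM2 were the 2 called of 24 repressors, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.976; median −0.04, mean 0.05, test positive).

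Clock genes were lower as a set in mbd8, 20 of 23 being below 0 (camera adjusted p = 1.34e-05; adjusted p = 0.329 with an estimated correlation). LNK2, a clock coactivator, was the 1 that fell (−0.38, adjusted p = 0.0316), and 3 fell when adjusted over the list alone; LNK2 was lost without C24 replicate 1 (0.131), C24 replicate 2 (0.181) or mbd8 replicate 1 (0.103). Salicylic acid defence genes were higher as a set, 19 of 20 being above 0 (camera adjusted p = 2.08e-07; adjusted p = 0.34 with an estimated correlation), and 9 rose when adjusted over the list alone. Over all genes 2 rose, PR5 (0.72, adjusted p = 0.0296) and WRKY70 (0.53, adjusted p = 0.0253). Both were lost without C24 replicate 1 (0.099) or C24 replicate 2 (0.164), and PR5 also without mbd8 replicate 1 (0.0883). Photosynthesis genes were lower as a set, 19 of 20 being below 0 (median −0.15, camera adjusted p = 2.08e-07; adjusted p = 0.34 with an estimated correlation), with 0 limma calls and 12 lower at an unadjusted p under 0.05. Flavonoid and anthocyanin genes were higher as a set (median 0.44, camera adjusted p = 4.73e-05; adjusted p = 0.34 with an estimated correlation), with 0 limma calls of 13, 7 at an unadjusted p under 0.05 and 6 adjusted over the list alone. Cold, drought and abscisic acid genes were higher as a set (camera adjusted p = 0.0018; adjusted p = 0.486 with an estimated correlation), which was lost without mbd8 replicate 3 (0.283). ERD10 was the 1 call of 24 and the 1 over the list alone (0.30, adjusted p = 0.0396), lost without any C24 replicate or mbd8 replicates 1 or 3 (0.0627 to 0.199).

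ROS1 was the 1 called of 38 histone and DNA methylation enzymes, over all genes and over the list alone (camera adjusted p = 0.189). The families of the mutated genes (camera adjusted p = 0.471), jasmonate response (0.189, with 1 higher over the list alone), heat shock proteins (0.976), iron homeostasis (0.976), glucosinolate synthesis (0.0584), root markers (0.0719) and seed markers (0.904) did not pass. Single libraries decided 4 of these. Jasmonate response passed without C24 replicate 1 (0.00217), and glucosinolate synthesis without C24 replicate 3 (0.0287), mbd8 replicate 1 (0.0272) or mbd8 replicate 2 (0.000198). Root markers passed without C24 replicate 2 (0.0133) or mbd8 replicate 3 (0.0432), and seed markers without C24 replicate 2 (0.0165). ASN1, an asparagine synthetase, fell from 3698 ± 1011 to 1851 ± 209 (−0.97, SE 0.145, adjusted p = 0.0139), lost without C24 replicate 1 (0.0889) or mbd8 replicate 1 (0.0542). APK4, an APS kinase of sulphur assimilation, fell by 1.17 (adjusted p = 0.0394), lost without any 1 of the 6 libraries (0.0657 to 0.164).

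Genes annotated with translation made up 33 of the 67 annotated genes that rose in mbd8, against 2.72 expected (Fisher's exact test, adjusted p = 2.72e-26), among them the ribosomal protein genes RPL18, RPL24A and RPS28, and ribosome biogenesis made up 16 (adjusted p = 1.8e-15). Neither phrase held in every run with 1 library left out, and the number of all calls moved with them. Annotated genes called higher were 2 without C24 replicate 1, 4 without C24 replicate 2 and 13 without mbd8 replicate 1, so few were left to test. Without C24 replicate 1 and without C24 replicate 2, limma called 0 genes of either phrase. Without mbd8 replicate 1 it called 1 of translation and 0 of ribosome biogenesis, with an adjusted p of 1 in each of these runs. Without mbd8 replicate 3 it called 7 (adjusted p = 0.0195) and 4 (adjusted p = 0.0283), and without mbd8 replicate 2 it called 57 of translation. In total 152 genes passed in mbd8, 104 higher and 48 lower, of which 12 changed at least 2-fold, and 2923 had an unadjusted p under 0.05. The groups did not overlap for 18.9% of the genes, against 10% by chance. The 152 became 9 without C24 replicate 1 (6 higher and 3 lower), 10 without C24 replicate 2 (7 and 3), 34 without mbd8 replicate 1 (26 and 8) and 89 without mbd8 replicate 3 (45 and 44). It was 10 with only C24 and mbd8 in the fit (8 and 2), and 80 with a pseudocount of 0.1 and no filter (58 and 22). With the replicate number as a block it was 680 (423 and 257). Within 2 Mb of MBD8, 5 of 760 genes changed (Fisher's exact p = 1), and the smallest adjusted p over windows of 1 Mb was 0.372.

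The direct contrast of mbd8 with ldl2 asked where the mutants of the proposed partners differ. ARP9 was higher in mbd8, at 537 against 213 in ldl2 (log2 fold change 1.34, SE 0.113, adjusted p = 8e-05), close to its C24 level of 548. AT1G67105, a gene on chromosome 1 (25057479 to 25058264), was lower, at 438 ± 37.1 against 1408 ± 60.6 (−1.68, SE 0.086, adjusted p = 1.82e-07). Its C24 libraries held 317.5, 382.6 and 342.2, below every library of both mutants, so mbd8 lay nearer to C24 than ldl2 did. TEM2 was lower in mbd8 than in ldl2 (−0.69, adjusted p = 0.0252), as were ORA47 (−1.55, adjusted p = 0.04) and DIC2 (−1.46, adjusted p = 0.0154), and LDL2 was higher (0.87, adjusted p = 0.0286). TEM1 did not pass (−0.37, adjusted p = 0.211). TEM2 was lost without ldl2 replicate 2 (0.14), ldl2 replicate 3 (0.12) or mbd8 replicate 1 (0.0974), DIC2 without the same libraries (0.0987 to 0.108), and ORA47 and LDL2 without these or mbd8 replicate 2 (0.0516 to 0.185 and 0.0673 to 0.141). AOC2, an enzyme of jasmonate synthesis, was higher (0.55, adjusted p = 0.0286), lost without any ldl2 replicate or mbd8 replicate 1 (0.0508 to 0.147).

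Between the mutants the flowering repressors were lower in mbd8 as a set, 21 of 24 being below 0 (camera adjusted p = 0.0125; adjusted p = 0.455 with an estimated correlation; lost without mbd8 replicate 2, 0.0603). TEM2 was their 1 call, over all genes and over the list alone. The clock list was lower (camera adjusted p = 0.0215; adjusted p = 0.718 with an estimated correlation), with 0 limma calls, 1 at an unadjusted p under 0.05, and was lost without ldl2 replicate 2 (0.0586) or mbd8 replicate 3 (0.0777). Salicylic acid genes were higher (camera adjusted p = 0.0125; adjusted p = 0.718 with an estimated correlation), with 0 limma calls, 4 at an unadjusted p under 0.05 and 1 over the list alone, and were lost without ldl2 replicate 3 (0.297) or mbd8 replicate 2 (0.695). Jasmonate response had 2 higher, over all genes and over the list alone, AOC2 and LOX2 (0.44, adjusted p = 0.0286; camera adjusted p = 0.0696), and the set passed without ldl2 replicate 2 (0.000429) or mbd8 replicate 1 (0.0288). Cold, drought and abscisic acid response had RD26 lower (−0.57, adjusted p = 0.0386), with 5 lower adjusted over the list alone (camera adjusted p = 0.196), and the set passed without ldl2 replicate 2 (0.00298) or mbd8 replicate 3 (0.00128). LOX2 and RD26 were lost without any ldl2 replicate or mbd8 replicates 1 or 2 (0.0516 to 0.128 and 0.0713 to 0.175). ROS1 was the 1 called methylation enzyme, over all genes and over the list alone (−0.45, lower, adjusted p = 0.0154), lost without ldl2 replicate 2 (0.0784) or ldl2 replicate 3 (0.104). Lists whose median, mean and test differed in sign were histone and DNA methylation enzymes (median 0.01, mean −0.01, test positive, adjusted p = 0.932), the families of the mutated genes (−0.03, 0.03, negative, 0.842, with LDL2 as the 1 call by both counts), photosynthesis (below 0, 0.02, positive, 0.407, with 1 higher over the list alone) and root markers (−0.01, 0.09, positive, 0.563). Flowering promoters (0.675), heat shock proteins (0.335), iron homeostasis (0.335), flavonoid (0.305), glucosinolate (0.335) and seed markers (0.376) did not pass. Heat shock proteins passed without mbd8 replicate 3 (0.0117), glucosinolate synthesis without mbd8 replicate 3 (0.0014) and iron homeostasis without mbd8 replicate 2 (0.0363).

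In total 108 genes differed between mbd8 and ldl2, 16 higher and 92 lower in mbd8, of which 20 differed at least 2-fold. Groups did not overlap for 17.76% of the genes, against 10% by chance. The 108 became 6 without ldl2 replicate 2 (1 higher and 5 lower), 4 without ldl2 replicate 3 (1 and 3), 6 without mbd8 replicate 1 (1 and 5) and 208 without mbd8 replicate 3 (51 and 157), and the 16 higher became 9 without ldl2 replicate 1. With only the 2 mutants in the fit it was 51 (3 and 48). With the replicate number as a block it was 539 (214 and 325). Genes annotated with the response to chitin were enriched among the lower ones (5 of 53, Fisher's exact test, adjusted p = 0.000301), and limma called 0 of them without ldl2 replicate 2, ldl2 replicate 3 or mbd8 replicate 1.

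Both Arabidopsis mutants shared 22 genes that rose and 4 that fell, and limma called 0 genes in opposite directions. Independent lists would share 0.848 and 0.0889. Simulated libraries with no changed gene and a shared wild-type group had 0.02 shared calls on average and 2 at most in 100 draws. Those draws do not measure what the real C24 libraries add. Shared rises included AT2G15555, CAF1a, ERF104, the auxin-responsive factor MYB77 (log2 fold change 1.44 in ldl2, 0.84 in mbd8), the potassium transporter HAK5 (1.31 and 0.98), the kinase MKK9 (0.99 and 0.55), TEM1, TEM2 and ERD10. In the same libraries the touch and rapid wound genes had a median of 1.25 in ldl2 and 0.39 in mbd8. Handling at harvest was therefore not separated from the mutations for the shared rises. Shared falls were AT4G38860 (−0.45 and −0.51), AT3G29180, AT2G42750 and THI2.2, and all were lost in ldl2 without C24 replicates 1 or 2 or ldl2 replicates 2 or 3, AT3G29180 and THI2.2 also without either of the other 2 libraries and AT2G42750 also without ldl2 replicate 1 (0.0782 to 0.105 for AT4G38860, 0.0536 to 0.186 for AT3G29180, 0.121 to 0.203 for AT2G42750 and 0.0767 to 0.186 for THI2.2). In mbd8 AT4G38860 was lost without C24 replicates 1 or 2 (0.099 and 0.164), AT3G29180 without any C24 replicate or mbd8 replicates 1 or 3 (0.0544 to 0.212), AT2G42750 without C24 replicates 1 or 2 or any mbd8 replicate (0.0515 to 0.22), and THI2.2 without any C24 replicate or mbd8 replicates 1 or 2 (0.0515 to 0.169). Of the 22, 7 also differed between the mutants. Fold changes correlated at 0.539 across genes, against 0.5002 with the simulated shared controls, and their covariance was 0.0372 against 0.0212, a difference of 0.0159. The 26 shared genes became 5 without C24 replicate 1, 6 without C24 replicate 2, 14, 17 and 15 without ldl2 replicates 1, 2 and 3, and 16 without mbd8 replicate 3. They became 6 with only the 2 groups of each comparison in the fit, 17 with no filter and 13 with a pseudocount of 0.1 and no filter. With the replicate number as a block they became 132, 84 that rose and 48 that fell. With libraries left out, the 22 rises became 5 without C24 replicate 1, 6 without C24 replicate 2, 13 without ldl2 replicate 1 and 14 without mbd8 replicate 3. The 4 falls became 0 to 2 by limma without C24 replicates 1 or 2, any ldl2 replicate or mbd8 replicates 1 or 3, 7 without mbd8 replicate 2 and 16 without C24 replicate 3.

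**Figure D2:**
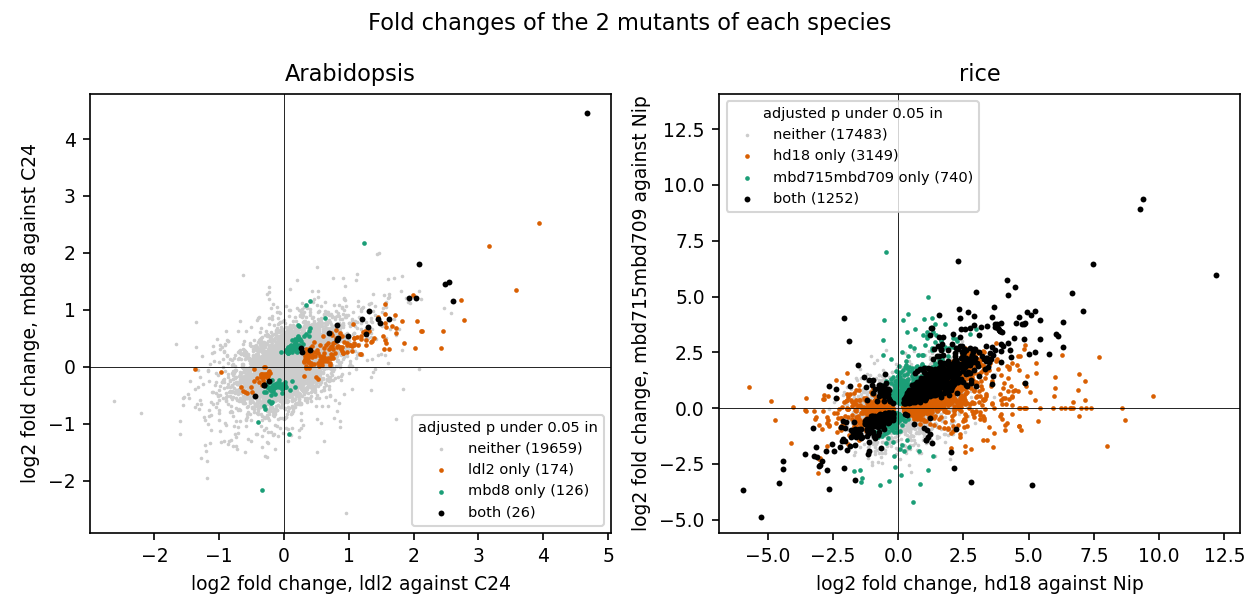
Log2 fold change of every tested gene in the 2 mutants of each species against their wild type, with Arabidopsis on the left (ldl2 on the x axis, mbd8 on the y axis) and rice on the right (hd18 on the x axis, mbd715mbd709 on the y axis), coloured by where the adjusted p was under 0.05. The 26 shared Arabidopsis genes lie in the quadrants of equal sign, and 1196 rice genes do so against 56 of opposite sign.

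The comparison of hd18 with Nip asked the same of rice HD18. HD18 (Os08g0143400) fell from 656 ± 36.9 in Nip to 304 ± 29.6 in hd18 (log2 fold change −1.11, SE 0.125, adjusted p = 1.3e-05), with 313.8, 270.9 and 327.6 in single libraries. Hd3a (Os06g0157700), a florigen gene, fell from 115.6 ± 42.6 to 29.6 ± 12.5 (−1.96, SE 0.388, adjusted p = 0.00219). OsMADS18, a MADS-box gene of the AP1/FUL type, fell from 1256 ± 229 to 821 ± 42.7 (−0.60, SE 0.115, adjusted p = 0.00178). These calls held without each library in turn.

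Of 13 tested flowering promoters 4 fell in hd18, and 5 did when adjusted over the list alone. The set did not pass by camera (adjusted p = 0.166; 0.362 with an estimated correlation), but it was lower by fry (adjusted p = 0.0264). Among the 4, OsMADS50 (−0.26, adjusted p = 0.0425) was lost without Nip replicates 1 or 2 or any hd18 replicate (0.0508 to 0.176). Of 13 repressors, OsMADS55 (0.44, adjusted p = 0.00207) and OsMADS47 (0.34, adjusted p = 0.00648) rose and OsCO3 fell (−0.41, adjusted p = 0.00476), the same counts as over the list alone (camera adjusted p = 0.445). Ghd7, a repressor under long days, did not pass (0.20, adjusted p = 0.651), Ehd1 was under the filter with values of 0.01 to 6.93, and Hd1 was listed at 0 in every library. Overlap with other genes was not checked in rice, so that 0 does not show that Hd1 is silent. Clock genes did not move as a set (camera adjusted p = 0.849; median −0.02, mean 0.04, test negative). OsELF4A (0.29, adjusted p = 0.0404) and OsFKF1 (0.44, adjusted p = 0.0426) rose and OsELF3-1 fell (−0.23, adjusted p = 0.049), with the same counts over the list alone, but OsELF4A was lost without Nip replicates 1 or 2 or hd18 replicates 1 or 3 (0.092 to 0.144), and OsFKF1 (0.0638 to 0.162) and OsELF3-1 (0.108 to 0.168) without Nip replicates 2 or 3 or any hd18 replicate.

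**Figure D3:**
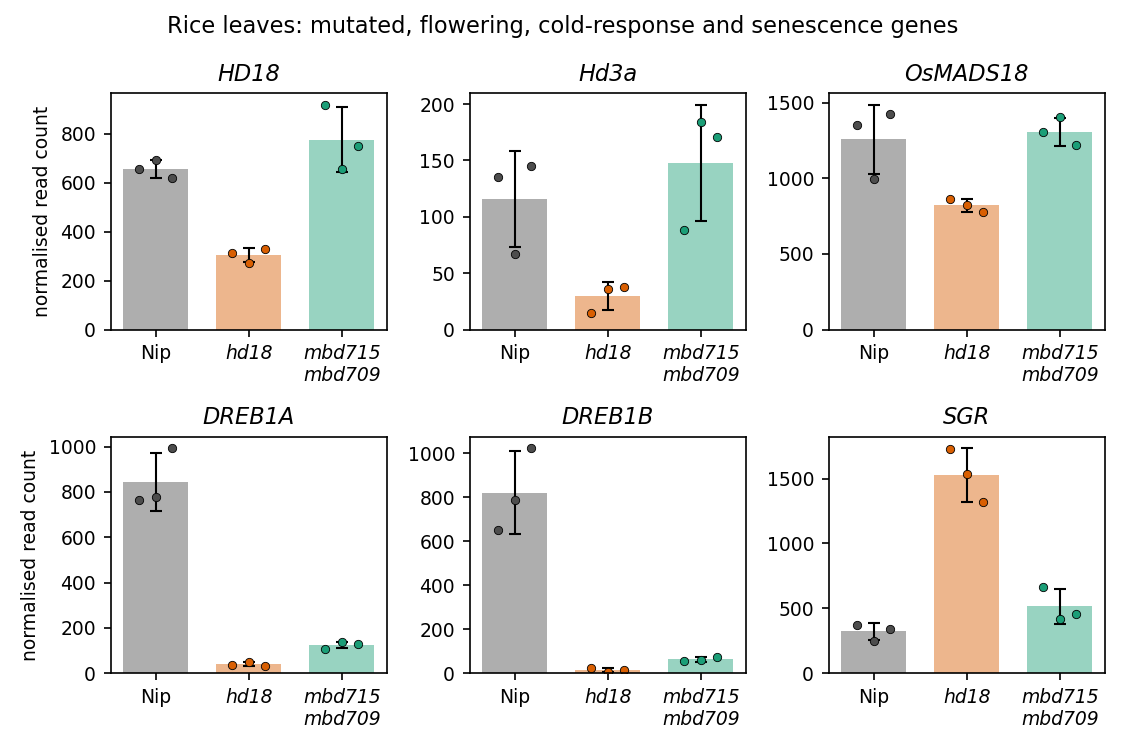
Library-size equalised read counts of HD18, Hd3a, OsMADS18, DREB1A, DREB1B and SGR in leaves of Nip, hd18 and mbd715mbd709; bars are means, error bars are the SD over 3 libraries and points are single libraries. Hd3a was lower in hd18, with a mean of 29.6, and DREB1A and DREB1B were lower than in Nip in both mutants.

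Defence and phytoalexin genes rose widely in hd18. Of 23 tested, 19 rose, and 20 did when adjusted over the list alone (median log2 fold change 3.12, camera adjusted p = 4.83e-15; adjusted p = 0.362 with an estimated correlation). By fry the set was higher at an adjusted p of 0.0071. RSOSPR10, of the PR10 family, went from 447 ± 143 to 5478 ± 1307 (3.64, SE 0.259, adjusted p = 9.49e-08). KSL8, a diterpene synthase, went from 55.1 ± 17.36 to 502 ± 171 (3.17, SE 0.256, adjusted p = 4.6e-07), and the cytochromes P450 CYP76M7 and CYP99A3 of the same phytoalexin pathways rose by 3.98 (adjusted p = 1.82e-06) and 2.49 (adjusted p = 1.54e-06). The calls were 18 to 21 in each run with 1 library left out. In Nip replicate 2 PR1A stood at 0.55, against 78.4 and 119 in the other Nip libraries, and KSL10 at 0.65 against 36.4 and 279.

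Senescence genes were higher in hd18 as a set, 7 of 7 being above 0 (camera adjusted p = 0.00311; adjusted p = 0.362 with an estimated correlation), with 2 called and 5 adjusted over the list alone. Fry gave this set an adjusted p of 0.00719. SGR, the stay-green gene of chlorophyll breakdown, rose from 322 ± 65.7 to 1528 ± 206 (2.25, SE 0.172, adjusted p = 2.32e-07), and NOL rose by 0.23 (adjusted p = 0.0411), lost without any 1 of the 6 libraries (0.0576 to 0.122), so that the count became 1. Of 12 drought and abscisic acid genes 5 rose and 3 fell, over all genes and over the list alone (camera adjusted p = 0.849). SALT (4.098, adjusted p = 4.01e-05), DIP1 (1.18, adjusted p = 3.46e-05) and the bZIP factor gene BZIP23 (0.89, adjusted p = 2.37e-05) rose. DREB1A and DREB1B, CBF-type factors of the cold response, fell, DREB1A from 845 ± 129 to 39.5 ± 8.92 (−4.40, SE 0.196, adjusted p = 4.5e-10) and DREB1B from 821 ± 188 to 14.3 ± 8.82 (−5.94, SE 0.387, adjusted p = 3.41e-08), and the NAC factor SNAC1 fell by 0.96 (adjusted p = 1.03e-06). The camera test was positive and the fry test negative for this list.

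Photosynthesis genes did not move as a set in hd18 (camera adjusted p = 0.445). LHCB1.3 rose (1.62, adjusted p = 0.000168) and RCA, Rubisco activase, fell (−0.65, adjusted p = 0.00731), the same counts as over the list alone; RCA was lost without hd18 replicate 3 (0.0529). Among histone and DNA methylation enzymes OsROS1A rose (0.23, adjusted p = 0.0299), lost without any Nip replicate or hd18 replicates 2 or 3 (0.0528 to 0.115), with 0 limma calls over the list alone and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.85). OsMADS1 was the 1 of 4 floral organ markers that fell (−1.13, adjusted p = 0.0426), lost without Nip replicates 1 or 2 or hd18 replicates 1 or 3 (0.091 to 0.188), and the list did not pass (camera adjusted p = 0.849; median 0.16, mean 0.22, test negative). Heat shock proteins (0.849) and the families of the mutated genes (0.497; median 0.06, mean −0.30, test negative) did not pass as sets. Of the latter HD18 was the 1 call by both counts, with OsLDL1 at 0.15 (adjusted p = 0.553) and MBD707 at 0.06 (adjusted p = 0.634), and no meristem marker reached the filter in any comparison.

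In total 4401 of 22624 genes passed in hd18, 2618 higher and 1783 lower, of which 1408 changed at least 2-fold. Groups did not overlap for 38.0% of the genes, against 10% by chance. The 4401 became 2819 without hd18 replicate 1 (1713 higher and 1106 lower) and 2927 without hd18 replicate 2 (1826 and 1101), and the 1783 lower became 1095 without Nip replicate 2. Os03g0115800 was listed at 0 in every Nip library and at 4652 ± 191 in hd18, and Os01g0186900 fell from 322 ± 102 to 9.43 ± 7.16 (−5.25, adjusted p = 6.56e-06).

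The comparison of mbd715mbd709 with Nip asked the same of the rice MBD genes. Hd3a did not pass here. It stood at 147.7 ± 51.6 against 115.6 ± 42.6 in Nip (log2 fold change 0.36, SE 0.388, adjusted p = 0.627). HD18 did not pass either (0.23, adjusted p = 0.285). DREB1A fell to 125 ± 14.7 from 845 ± 129 (−2.75, SE 0.196, adjusted p = 2.96e-07) and DREB1B to 62.8 ± 9.97 from 821 ± 188 (−3.68, SE 0.387, adjusted p = 2.08e-05), and KSL8 rose to 688 ± 163 from 55.1 ± 17.36 (3.65, SE 0.256, adjusted p = 2.72e-07).

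Of the 23 defence and phytoalexin genes 8 rose and 1 fell in mbd715mbd709, and 14 rose and 1 fell when adjusted over the list alone (median 1.05, camera adjusted p = 3.08e-07; adjusted p = 0.837 with an estimated correlation). CYP76M7 (3.42, adjusted p = 2.53e-05), CPS4, a diterpene cyclase (3.13, adjusted p = 0.000342), and RSOSPR10 (2.36, adjusted p = 2.86e-05) rose, and WRKY71 fell (−0.88, adjusted p = 0.000377). The 8 became 5 without Nip replicate 2, 5 without mbd715mbd709 replicate 1 and 12 without mbd715mbd709 replicate 3. Drought and abscisic acid genes were lower as a set (camera adjusted p = 0.0163; adjusted p = 0.335 with an estimated correlation), which was lost without mbd715mbd709 replicate 2 (0.0748). DREB1A, DREB1B and SNAC1 (−0.51, adjusted p = 0.0013) were the 3 that fell of 12, and 2 rose and 4 fell when adjusted over the list alone.

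Among senescence genes SGR rose in mbd715mbd709 (0.66, adjusted p = 0.026), lost without Nip replicate 2 (0.118) or mbd715mbd709 replicate 1 (0.0694), and the NAC factor NAP fell (−0.60, adjusted p = 0.0047), with 1 of each also over the list alone (camera adjusted p = 0.957). SDG725, a histone methyltransferase, was the 1 of 13 flowering promoters that fell (−0.22, adjusted p = 0.0472), lost without any Nip replicate or mbd715mbd709 replicates 2 or 3 (0.0558 to 0.139). Over that list alone limma called 0, and 3 had an unadjusted p under 0.05 (camera adjusted p = 0.874; median 0.02, mean 0.20, test negative). OsMADS55 was the 1 repressor that rose, also over the list alone (0.41, adjusted p = 0.00802; camera adjusted p = 0.438), and Ghd7 did not pass (0.21, adjusted p = 0.688). OsELF4A was the 1 clock gene that rose (0.34, adjusted p = 0.0349; camera adjusted p = 0.438), with 1 higher and 2 lower over the list alone, and was lost without any Nip replicate or mbd715mbd709 replicates 1 or 3 (0.0514 to 0.0993). LHCB1.3 was the 1 photosynthesis gene that rose, also over the list alone (1.16, adjusted p = 0.00616; camera adjusted p = 0.438). Without mbd715mbd709 replicate 1 the photosynthesis list passed (8.39e-05), with CAB2R (0.60, adjusted p = 0.00717) and RBCS2 (0.48, adjusted p = 0.00185) called higher, and the repressor list passed as well (0.0308). The families of the mutated genes (0.438), histone and DNA methylation enzymes (0.543), heat shock proteins (0.874) and floral organ markers (0.888; median −0.07, mean −0.04, test positive) did not pass.

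In total 1993 genes passed in mbd715mbd709, 1302 higher and 691 lower, of which 603 changed at least 2-fold. Groups did not overlap for 25.9% of the genes, against 10% by chance. The 1993 became 1098 without Nip replicate 2 (804 higher and 294 lower), 1305 without Nip replicate 3 (940 and 365) and 1185 without mbd715mbd709 replicate 3 (804 and 381). With only Nip and mbd715mbd709 in the fit it was 914 (643 and 271).

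**Figure D4:**
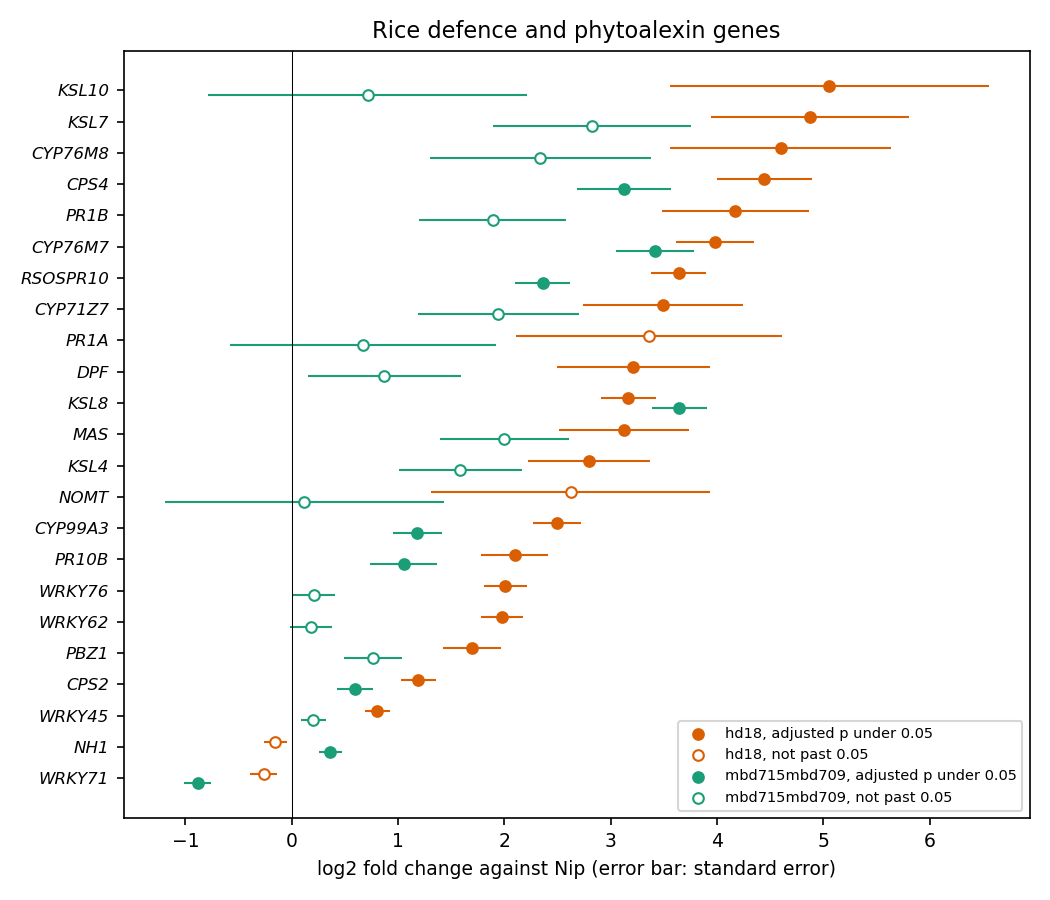
Log2 fold change against Nip of the 23 tested defence and phytoalexin genes in hd18 and mbd715mbd709, with standard errors; filled points have an adjusted p under 0.05. 19 genes rose in hd18, and 8 rose and 1 fell in mbd715mbd709.

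The direct contrast of mbd715mbd709 with hd18 asked where the rice mutants differ. Hd3a was higher in mbd715mbd709 than in hd18 (log2 fold change 2.32, SE 0.388, adjusted p = 0.00117), as was OsMADS18 (0.67, adjusted p = 0.00145), and these calls held without each library in turn. HD18 was higher by 1.34. Of 13 flowering promoters 3 were higher and 1 lower, and 4 and 2 over the list alone (camera adjusted p = 0.123). The lower one, OsMADS51 (−0.33, adjusted p = 0.0392), was lost without any hd18 replicate or mbd715mbd709 replicates 1 or 3 (0.085 to 0.158).

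Defence and phytoalexin genes were lower in mbd715mbd709 than in hd18, 8 of 23 by the test and 13 over the list alone (median −1.31, camera adjusted p = 7.23e-09; adjusted p = 0.293 with an estimated correlation). WRKY62 (−1.80, adjusted p = 2.2e-05), WRKY45 (−0.60, adjusted p = 0.00336) and CYP99A3 (−1.31, adjusted p = 0.0015) were lower, and NH1, the rice relative of NPR1, was the 1 that was higher, also over the list alone (0.52, adjusted p = 0.00619). The 8 became 15 without mbd715mbd709 replicate 1. Senescence genes were lower, 7 of 7 being below 0 (camera adjusted p = 0.000103; adjusted p = 0.293 with an estimated correlation), with SGR (−1.59), NAP (−0.85) and NOL (−0.32) called over all genes and 3 also over the list alone; NOL was lost without hd18 replicate 2 (0.0506). Of 12 drought and abscisic acid genes 3 were higher and 6 lower by both counts (camera adjusted p = 0.123), SALT among the lower (−5.06, adjusted p = 1.15e-05). Photosynthesis genes were higher as a set (camera adjusted p = 0.0259; adjusted p = 0.631 with an estimated correlation), with 0 limma calls of 19 and 3 at an unadjusted p under 0.05, and were lost without hd18 replicate 2 (0.0551), hd18 replicate 3 (0.175), mbd715mbd709 replicate 2 (0.454) or mbd715mbd709 replicate 3 (0.0937).

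Among histone and DNA methylation enzymes SDG714 was higher (0.90, adjusted p = 0.0129) and OsROS1A lower (−0.35, adjusted p = 0.00516), by both counts (camera adjusted p = 0.559; median −0.02, mean 0.07, test negative), and SDG714 was lost without hd18 replicate 1 (0.0699) or mbd715mbd709 replicate 3 (0.0509). The families of the mutated genes (0.0937, with HD18 called), flowering repressors (0.926; median 0.00, mean −0.01), clock (0.508), heat shock proteins (0.508) and floral organ markers (0.559; median 0.20, mean −0.25, test positive, 1 higher over the list alone) did not pass. In total 1923 genes differed, 959 higher and 964 lower in mbd715mbd709, of which 673 differed at least 2-fold. Groups did not overlap for 26.69% of the genes, against 10% by chance. The 1923 became 1227 without hd18 replicate 1 (701 higher and 526 lower), 1091 without hd18 replicate 2 (569 and 522), 1182 without hd18 replicate 3 (594 and 588), 3007 without mbd715mbd709 replicate 1 (1512 and 1495) and 1184 without mbd715mbd709 replicate 3 (569 and 615). The 964 lower became 642 without mbd715mbd709 replicate 2.

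The rice mutants shared 846 genes that rose and 350 that fell, with 56 in opposite directions. Independent lists would share 151 and 54.5. Simulated libraries with no changed gene and a shared wild-type group had 0.07 shared calls on average and 1 at most in 100 draws. Those draws do not measure what the real Nip libraries add. DREB1A, DREB1B and SNAC1 were among the shared falls, and KSL8, CYP76M7 and RSOSPR10 among the shared rises. Os04g0397800 was listed at 0 in every Nip library and stood at 682 ± 122 in hd18 and 670.5 ± 87.9 in mbd715mbd709, and Os03g0678800 fell from 115 ± 24.3 to 3.88 ± 0.91 and 10.3 ± 0.552. Of the shared genes, 132 that rose and 67 that fell also differed between the mutants. Fold changes correlated at 0.559 across genes, against 0.5004 with the simulated shared controls, with a covariance of 0.231 against 0.0475, a difference of 0.183. The 1196 shared genes became 623 with only the 2 groups of each comparison in the fit (424 that rose and 199 that fell) and 709 without Nip replicate 2 (556 and 153), and the 350 falls became 224 without Nip replicate 3, 227 without hd18 replicate 2 and 220 without mbd715mbd709 replicate 3.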

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

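The tests of sampling time and leaf condition in this part were chosen only after the result was seen. The results below stood out because the 2 mutants of a species differed from each other in the direct limma contrast. TEM2 was 1 of them in Arabidopsis, with a log2 fold change of −0.689 between mbd8 and ldl2 (adjusted p = 0.0252), and that call was lost without ldl2 replicate 2 (0.14), ldl2 replicate 3 (0.12) or mbd8 replicate 1 (0.0974). The touch and rapid wound genes also had a higher median in ldl2 (1.25) than in mbd8 (0.39), so handling at harvest stays open for TEM2. In rice, Hd3a (2.315) and OsMADS18 (0.67) were higher in mbd715mbd709 than in hd18. Groups of 3 libraries were not tested for outlying samples.

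Hd3a was lower in hd18 than in Nip, and its level follows the time of day and the state of the leaf. Sampling at another time of day stayed open, although some clock genes were held close to 0. The 95% intervals reached at most 0.196 from 0 for OsLHY, 0.165 for OsGI and 0.226 for OsPRR1 on the log2 scale. They reached at most 0.184 for OsPRR37, 0.241 for OsPRR95, 0.255 for OsPRR59 and 0.26 for OsPRR73. These values argue against a shift of 0.5 in those genes. The 95% intervals of 12 of 15 tested clock genes lay within 0.5 of 0 on the log2 scale, but the widest, that of OsLUX, reached 1.05, and OsFKF1 (0.44) and OsELF4A (0.29) were called higher and OsELF3-1 (−0.23) lower, OsELF4A being lost without Nip replicates 1 or 2 or hd18 replicates 1 or 3 (0.092 to 0.144), and OsFKF1 (0.0638 to 0.162) and OsELF3-1 (0.108 to 0.168) without Nip replicates 2 or 3 or any hd18 replicate. Leaf condition also stayed open, since 19 of 23 defence genes rose in hd18, while 8 rose (5 without Nip replicate 2 or mbd715mbd709 replicate 1, 12 without mbd715mbd709 replicate 3) and 1 fell in mbd715mbd709, where Hd3a did not pass (medians 3.12 and 1.05; set tests at adjusted p = 0.362 and 0.837 with an estimated correlation). Time of day and leaf condition cannot be told apart from a direct effect of the HD18 mutation, which remains a hypothesis. The clock intervals leave shifts under 0.5 possible, and larger ones for OsLUX, OsFKF1 and OsELF3-2. For leaf condition, the defence genes moved less in mbd715mbd709, so that mutant does not settle the question.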

How the results depend on the processing

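The voom settings and the pseudocount of 0.1 with the filter kept were chosen after seeing the data. The count tests planned for raw counts (edgeR with a second scaling, and DESeq2) were not run, because the tables hold equalised values. Where no construction is named, the cause was not tested. With only the 2 groups compared, which leaves fewer libraries for the spread, the counts were 313 for ldl2 (200 in the fit of 9 libraries), 10 for mbd8 (152), 51 for mbd8 against ldl2 (108), 914 for mbd715mbd709 (1993), and 6 and 623 for the shared calls (26 and 1196). A pseudocount of 0.1 without a filter gave 80 for mbd8 and 13 shared Arabidopsis calls, and no filter gave 17; with the filter kept that pseudocount gave 149 and 26. At an adjusted p of 0.01 the shared calls were 5 and 486. Lists past the threshold (7 for ldl2, 5 for mbd8, 3 for mbd8 against ldl2, 2, 2 and 3 in rice) became 0 in all 6 comparisons with an estimated correlation. Fry gave 0 in the 3 Arabidopsis comparisons and 5 in hd18. Those 5 were the families of the mutated genes, flowering promoters, defence and phytoalexin synthesis, drought and abscisic acid response, and leaf senescence. Fry reversed the rice drought and abscisic acid list in hd18 (adjusted p = 0.0264, negative), whose adjusted p ranged from 0.0264 to 0.981 over its alternatives. Annotation phrases past the threshold became 0 for the higher genes of ldl2 and of mbd8 and for the lower genes of mbd8 against ldl2 when calls also needed a 2-fold change, which leaves fewer genes.

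Same-numbered replicates did not pair by the rule used. Their deviations correlated at 0.0048 to 0.232 in Arabidopsis and −0.146 to 0.0395 in rice, and every library correlated best with its own number only between mbd8 and ldl2. There each same-numbered pair (0.0968 to 0.232) lay above every other pair (0.0375 at most). Same-numbered Arabidopsis libraries still shared a structure, as a hint from the data: the correlations were 0.136 to 0.232 for numbers 2 and 3 and 0.0048 to 0.0968 for number 1, and in each genotype the first principal component (20.1% of the variance) was lowest in replicate 2 and highest in replicate 3. With the replicate number as a block the counts were 583 for ldl2 (342 higher and 241 lower), 680 for mbd8 (423 and 257), 539 for mbd8 against ldl2 (214 and 325), 132 shared Arabidopsis calls (84 and 48), and 5 lists past the threshold for mbd8 against ldl2. The lists gained were glucosinolate synthesis in mbd8 (adjusted p = 0.028) and jasmonate response (0.0367) and seed markers (0.038) in mbd8 against ldl2.

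Leaving out 1 library gave 76 to 178 genes for ldl2, 9 to 199 for mbd8, 4 to 208 for mbd8 against ldl2, 2819 to 3792 for hd18, 1098 to 2277 for mbd715mbd709 and 1091 to 3007 for mbd715mbd709 against hd18. Shared calls were 5 to 33 and 709 to 1179, and lists past the threshold 3 to 8, 5 to 7, 2 to 5, 2 to 2, 1 to 4 and 2 to 3. Voom over library totals shifted the split of higher and lower calls. It gave 221 and 18 for ldl2 (163 and 37 in the main fit), 184 and 42 for mbd8 (104 and 48) and 14 and 132 for mbd8 against ldl2 (16 and 92). In rice it gave 3182 and 912 for hd18 (2618 and 1783), 1090 and 411 for mbd715mbd709 (1302 and 691) and 699 and 1386 for mbd715mbd709 against hd18 (959 and 964). Its shared calls were 29 and 1 in Arabidopsis (22 and 4) and 715 and 228 in rice (846 and 350). With the fitted depth, voom gave 146 and 40, 96 and 43, 14 and 91, 2610 and 1791, 1134 and 682, and 1030 and 1082. Its shared calls were then 15 and 4 in Arabidopsis and 684 and 377 in rice. No scaling moved the median of all genes by more than 0.0855. Of 214 calls of named genes and list members, 138 stayed past the threshold under every setting and 0 reversed by limma. The next counts cover all 376 pairs of such a gene and a comparison, called or not. Over other settings 3198 of 3363 values stayed on their side of the threshold, 133 were weaker and 32 stronger. With 1 library left out 1950 of 2256 stayed, 292 were weaker and 14 stronger. A pair not called in the main fit counts as staying while it remains uncalled, and only calls can become weaker, so these shares overstate how well calls held. For lists with 1 library left out, 431 of 468 stayed.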

Other observations

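The tests of a single library and of sampling time, and those of a chromosome block and floral tissue, were chosen only after the result was seen, while the test of handling was written before its values were seen.

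Seed storage genes varied within groups of Arabidopsis seedlings. CRA1, a seed storage protein gene, stood at 101.7, 0 and 1089 in the 3 C24 libraries, 210, 30.2 and 276 in ldl2 and 106, 2.05 and 144 in mbd8. In each genotype replicate 2 held the lowest value.

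Genes annotated with the response to chitin were enriched among those that rose in ldl2, with 8 of 53 called (median of the 53 on the log2 scale 0.185, and 0.0907 in mbd8). One library as its carrier was argued against by the second highest median among ldl2 libraries, 0.216, although the medians were 0.0535, 0.288 and 0.216 in ldl2 and 0.0641, −0.0154 and 0.0129 in C24 (0.0302, 0.204 and −0.0249 in mbd8, replicate 2 being the highest of each mutant), so ldl2 replicate 1 was not above the highest C24 library; this test first asked whether every ldl2 library rose and was reworded after its values were seen. Handling at harvest is a candidate explanation that the data allow, since the 11 touch and rapid wound genes had a median of 1.25 in ldl2, 6 of them called (5 without ldl2 replicate 2). TCH3, CML37, CML38, WRKY33 and WRKY40 were not called. Of the 11, 0 carried the chitin phrase. Notes that gave only a number of processes yielded no phrase, so this does not show separate responses. Sampling at another time stayed open, as morning minus evening clock genes differed by −0.218 in ldl2 and −0.258 in mbd8. Handling and sampling time cannot be told apart from an effect of the ldl2 mutation, because each genotype may have been harvested as a unit. Harvest by replicate number across genotypes is also possible, since same-numbered libraries shared a structure. Their correlations were 0.136 to 0.232 for numbers 2 and 3, but 0.0048 to 0.0968 for number 1. The labels do not settle which was done.

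In rice, 38 genes had a mean under 1 in Nip and at least 20 in every hd18 library, against 2 the other way (exact binomial test, p = 1.49e-09), and mbd715mbd709 had 9 against 0, with 5 on in both mutants. That test takes the 40 genes as independent and an even split as its null, so its p does not measure the spread between libraries. Genes called with at least a 2-fold change in hd18 were also split unevenly, with 1171 higher and 237 lower. One introgressed chromosome block as the source of all 38 was argued against, as the largest share on any chromosome by identifier, that of chromosome 4, was 18.4% of them (7 genes, against 8.65% of tested genes), and the 38 lay on 10 chromosomes; clustering of neighbouring genes was not tested, so a block holding some of them stays open. Reads from floral tissue stayed open, as the 4 tested floral organ markers went both ways (from −1.13 to 1.70, median 0.156). The highest was OsMADS3, near the floor at 7.18, 4.33 and 0.03 in Nip and 5.07, 11.65 and 18.9 in hd18. The 1 called marker, OsMADS1, fell, and 3 listed markers were at 0 in every library. Another parental line of hd18 was not tested and stays open. Silent genes becoming active may be a consequence of the hd18 mutation, and this stays a hypothesis beside those open explanations.

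Other splits of the 6 libraries of each comparison number 10 with the real one, too few for a share under 0.05. In each comparison 1 split, the real one, reached the real count. The other splits mix libraries of both groups in each part, so a difference between the groups widens their spread and leaves few calls. Their low counts therefore do not show what chance would give. The real and the highest other counts were 200 and 0 for ldl2, 152 and 6 for mbd8, 108 and 0 for mbd8 against ldl2, 4401 and 0 for hd18, 1993 and 1 for mbd715mbd709, and 1923 and 0 for mbd715mbd709 against hd18, all by limma with Benjamini-Hochberg adjustment; the unadjusted counts of the real splits under 0.05 were 2447, 2923, 2528, 7201, 5506 and 5095.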
